A study of Homo sapiens with 10 samples.

How the data were processed

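RNA was measured in 10 libraries of HCT116 cells, per the labels: KDM5A-/- cells with empty vector (3), with a plasmid for wild-type KDM5A (3) or for a mutant KDM5A (2), and parental cells with empty vector (2). Per the labels, transfected cells were sorted for GFP after 24 hours, total RNA was taken with Trizol, and an Illumina sequencer of the NovaSeq or the HiSeq line was used, without saying which for each library. Per the labels the knockout culture alone held G418, so genotype, clone and G418 cannot be separated. The labels name STAR 2.7.1a, Picard, GATK 4.1.2, Cufflinks 2.2.1 and GRCh38, without the order of the tools, the annotation release or the strand setting.

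The authors deposited 1 table per library with a symbol, a locus and a log2 FPKM value, 60141 loci in the same order in every table, with 57993 different symbols. The values of each table show that the deposited log2 is taken of a value plus 1 and that these values sum to 999975 to 1000008 per library, so the authors' FPKM had been rescaled to a common total. No read counts were analysed here, and the depth behind each value and the counting precision it gives are unknown. Loci were matched to GENCODE release 29 by symbol and overlap (34280), by the same start and end only (21917) or by a reciprocal overlap of 90% only (316). Together this gave a gene type and exonic length to 56513 loci (94.0%).

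The deposited values were turned back to the linear scale, summed over loci with the same symbol, and divided by a factor per library, the median ratio to the geometric mean over libraries of the 13651 genes with a value of at least 1 in every library. Genes with a scaled value of at least 1 in at least 2 libraries were kept (17780). Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 read the files, and matplotlib 3.10.9 drew the figures. Differential expression was tested in R 4.3.3 with limma 3.58.1 (lmFit, contrasts.fit and eBayes with a trend) on log2(scaled value + 1), with all 10 libraries in 1 fit, 4 groups, 6 residual and 2.99 prior degrees of freedom. The test is two-sided, with Benjamini-Hochberg adjustment over the genes tested in each of the 4 comparisons, and a gene passed at an adjusted p under 0.05. Fold changes are on the log2 scale of the value plus 1 and means are of scaled values.

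Gene lists, comparisons, test, thresholds and the alternatives listed last were fixed before the data were examined, except where an alternative or test is said to have been chosen later. Of the 35 lists, 31 had at least 5 tested members and were tested with camera in limma, with a preset correlation between genes of 0.01 and with an estimated correlation, adjusted over the lists of a comparison. Members were also counted with adjustment over the list alone. The lists cover KDM5 paralogs, H3K4 methylation, genes described for KDM5A, cell cycle, p53, interferon, antigen presentation, NF-kB, immediate early genes, stress responses, metabolism, ribosomes, Wnt, Notch, differentiation, epithelial and mesenchymal genes, metallothioneins, apoptosis, DNA repair, histones, small RNAs, housekeeping, germline and HOX genes and markers of other cell types. Genes were named by rule: KDM5A, the 10 largest changes each way among genes that passed, did not overlap between groups and had a mean of at least 1, filled up to 5 by smallest p where fewer than 5 passed, up to 4 members of smallest p per list, and 5 genes that passed with both KDM5A plasmids. Uncharacterised loci and pseudogenes were in part counted without names. CA5B, PIR, AP1S2 and RP11-727F15.13 were chosen after their values were seen.

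The test was checked on simulated data with 200 changed genes among 17780, drawn from genes with a mean log2(scaled value + 1) over 2. The noise was independent between genes, so differences in library make-up were not simulated, and recovery in these data may be lower. Of genes changed by 0.5, 1 and 2 on the log2 scale it recovered 55.2%, 92.5% and 100% for wild-type KDM5A against empty vector with 9 false calls, 52.2%, 82.1% and 97.0% for mutant KDM5A against empty vector with 4, 44.8%, 86.6% and 98.5% for mutant against wild-type with 6, and 41.8%, 80.6% and 89.4% for parental against knockout cells with 15. Fold changes of comparison pairs that share controls were set against 100 draws of unchanged groups. Every group, controls included, was drawn as noise with 1 spread per gene, pooled over the 4 groups.

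The alternatives were the values as deposited, quantile normalization, pseudocounts of 0.1 and 0.5 in place of 1, no filter, a filter at a mean of 5, array weights, a fit of only the libraries compared, replicate numbers as a block, an adjusted p under 0.1, a log2 fold change of at least 1, protein-coding genes only, fry for the lists, and each library left out in turn. Alternatives chosen after seeing the data were a correction for gene length, the protein-coding share of each library as a covariate, the 3 libraries of lower protein-coding share left out, and quantile normalization for the lists.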

Results

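The series measured RNA in HCT116 cells, a human colorectal carcinoma line, and in a derivative of it labelled KDM5A-/-. KDM5A is a histone demethylase that removes methyl groups from lysine 4 of histone H3, and the title of the series concerns its methylation by the enzyme SMYD2. The knockout cells received an empty vector (3 libraries), a plasmid for wild-type KDM5A (3 libraries) or a plasmid for a mutant KDM5A (2 libraries), and the parental cells received the empty vector (2 libraries). The labels do not name the mutation. Cells positive for GFP were sorted 24 hours after transfection and their RNA was sequenced. Each of the 10 libraries gave 1 table of 60141 gene loci on a log2 FPKM scale whose linear values summed to about 1000000, so the number of reads behind a value is unknown. Between 15509 and 16272 symbols per library had a value of at least 1. Nothing states that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

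KDM5A (chromosome 12, 280129 to 389454, GRCh38) is given first, in every library, as the scaled linear value. It was 13.3 and 17.7 in the parental libraries and 12.2, 15.3 and 12.3 in the empty-vector libraries labelled KDM5A-/-. It was 13453, 16237 and 15599 with the wild-type plasmid and 23347 and 22817 with the mutant plasmid. The means were 15.5 ± 3.09 (SD, n = 2) in parental cells, 13.3 ± 1.78 (SD, n = 3) with empty vector, 15096 ± 1459 (SD, n = 3) with wild-type KDM5A and 23082 ± 375 (SD, n = 2) with mutant KDM5A. The parental and empty-vector knockout levels differed by less than the test could tell from the spread (log2 fold change 0.20, SE 0.13, adjusted p = 0.391). The log2 fold change was 0.01 without parental library 2 and 0.39 without parental library 1. A value over the whole gene therefore did not separate the knockout label from the parental label, as it can also count RNA from a disrupted locus, and it checks only the labels of the KDM5A plasmids. KDM5A was 1136 times its empty-vector level with the wild-type plasmid and 1736 times with the mutant plasmid. The mutant level was 1.53 times the wild-type level, a difference that did not pass the test over all genes (log2 fold change 0.62, SE 0.13, adjusted p = 0.0927). It passed without parental library 1 or parental library 2, with a log2 fold change of 0.62 each time. KDM5A RNA made up 1.38% to 1.99% of the library total in the 5 libraries with a KDM5A plasmid.

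**Figure D1:**
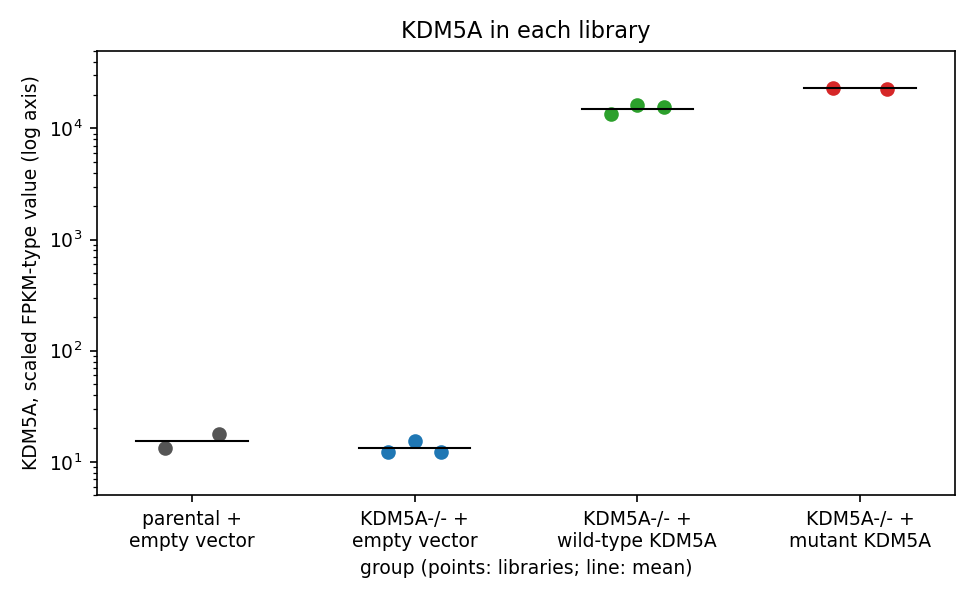
KDM5A in the 10 libraries as the scaled linear value on a log axis, with a point per library and a line at each group mean. The 5 libraries with a KDM5A plasmid lie between 13453 and 23347, and the 5 libraries with empty vector lie between 12.2 and 17.7.

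The comparison of wild-type KDM5A with empty vector in the knockout cells asks what changes within 24 hours of adding wild-type KDM5A from a plasmid. Genes of the interferon response, heat shock genes and the chemokine genes CXCL8 and CXCL3 rose, and KDM5B, EGR1 and several HOX genes fell. Of the 17780 genes tested, 448 were higher and 359 lower with wild-type KDM5A, together 4.54%. Among the largest rises, CXCL8, the neutrophil chemokine interleukin 8, went from 28.6 ± 1.77 (SD, n = 3) to 151 ± 2.40 (SD, n = 3) (log2 fold change 2.36, SE 0.09, adjusted p = 7.44e-06), and HSPA1A, an inducible HSP70 chaperone, went from 121 ± 5.62 (SD, n = 3) to 496 ± 24.0 (SD, n = 3) (log2 fold change 2.03, SE 0.14, adjusted p = 0.000165). KDM5B, a paralog of KDM5A, fell from 26.3 ± 0.597 (SD, n = 3) to 17.1 ± 1.52 (SD, n = 3) (log2 fold change -0.60, SE 0.07, adjusted p = 0.00480). The 10 largest rises also held HSPA1B (1.95), a near-identical copy of HSPA1A whose reads cannot be told from it with certainty, and the chemokines CXCL3 (1.90) and CCL20 (1.44). The same group held the iron-sequestering protein LCN2 (1.65), the interferon-induced gene IFI27 (1.51) and the transcription factor POU2F2 (1.45). The 10 largest falls held 7 loci that are not protein-coding, and the protein-coding genes among them included PMEPA1, an inhibitor of TGF-beta signalling (-1.15), and DBP, a clock-controlled transcription factor (-1.08).

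The gene lists fixed beforehand placed these genes in groups. Of the 41 tested interferon response genes, 17 were higher and 0 lower with wild-type KDM5A, or 24 higher when adjusted over the list alone. Camera gave adjusted p = 1.41e-18 with the preset correlation and adjusted p = 0.00227 with an estimated correlation. Examples are IFI6 (1.35), IFIT1 (1.16), IFIT2 (0.73) and the ubiquitin-like modifier ISG15 (0.77). Of the 18 antigen presentation genes, 4 were higher (7 adjusted over the list alone), among them HLA-F (0.69) and HLA-C (0.29). The antigen presentation list had adjusted p = 0.0288 with an estimated correlation. Of the 20 heat shock genes, 8 were higher and 0 lower (15 higher adjusted over the list alone), including the co-chaperones DNAJB1 (0.80) and BAG3 (0.46). The heat shock list had adjusted p = 0.0288 with an estimated correlation, and its median minus all genes went from 0.28 to 0.16 after quantile normalization. Of the 27 HOX genes tested, which pattern the body axis, 3 were lower and 0 higher (10 lower adjusted over the list alone), namely HOXB6 (-0.57), HOXB9 (-0.41) and HOXA7 (-0.41). The HOX list had adjusted p = 0.0185 with an estimated correlation. These 4 lists passed with both correlations. With the length correction, chosen after seeing the data, and an estimated correlation, 3 lists passed in this comparison. In every comparison, list tests with a library left out used the preset correlation only, so calls with an estimated one were not checked that way.

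Other lists passed camera with the preset correlation and not with an estimated one. In the NF-kB and inflammatory list, 7 of 22 genes were higher and 1 lower (8 and 1 adjusted over the list alone), including CXCL1 (1.32) and CXCL2 (1.39). The NF-kB list had adjusted p = 0.0511 with an estimated correlation. Among 32 p53 targets, 9 were higher and 1 lower (15 and 4 adjusted over the list alone), including the growth arrest gene GADD45A (0.81), the stress cytokine GDF15 (0.76) and the pro-apoptotic gene BBC3 (0.61). The p53 list had adjusted p = 0.12 with an estimated correlation. Among 27 integrated stress and unfolded protein response genes, 9 were higher and 2 lower (13 and 4 adjusted over the list alone), including the endoplasmic reticulum chaperone HSPA5 (0.57) and HERPUD1 (0.64). The integrated stress list had adjusted p = 0.0871 with an estimated correlation. Of 40 G2/M genes, 5 were lower and 0 higher (16 lower adjusted over the list alone), including CDC25B (-0.40) and the mitotic kinase CDK1 (-0.37). The G2/M list had adjusted p = 0.12 with an estimated correlation. Of 46 G1/S genes 1 was lower (3 adjusted over the list alone). The G1/S list had adjusted p = 0.0958 with an estimated correlation. Homologous recombination genes (2 of 33 lower, 4 adjusted over the list alone) had adjusted p = 0.0511 with an estimated correlation. None of the 69 ribosomal protein, 51 oxidative phosphorylation and 13 mitochondrially encoded genes passed (0 also adjusted over each list alone). The upward shift of these lists (adjusted p = 0.428, adjusted p = 0.560 and adjusted p = 0.442 with an estimated correlation) turned downward after quantile normalization. Mesenchymal genes had 2 of 24 higher and 1 lower (the same counts adjusted over the list alone). The mesenchymal list had adjusted p = 0.12 with an estimated correlation. Epithelial genes had 2 of 28 higher (7 higher and 1 lower adjusted over the list alone), with adjusted p = 0.12 with an estimated correlation and a median below 0 after quantile normalization. MYC targets had 1 of 35 higher and 1 lower (2 and 1 adjusted over the list alone), with adjusted p = 0.148 with an estimated correlation and a median below 0 after quantile normalization. Housekeeping controls had 1 of 20 higher (2 adjusted over the list alone), with adjusted p = 0.229 with an estimated correlation and a median below 0 after quantile normalization. With the preset correlation, MYC targets lost the call without empty-vector library 3 or wild-type library 3 (adjusted p = 0.0667 and 0.0540), as did mesenchymal genes (adjusted p = 0.0965 and 0.137). Oxidative phosphorylation lost it without empty-vector library 2 or 3 (adjusted p = 0.166 and 0.0745). The immediate early list did not pass (adjusted p = 0.743 with the preset correlation and adjusted p = 0.894 with an estimated correlation), with 4 of 35 genes higher and 6 lower (10 and 9 adjusted over the list alone). Its median was 0.01 and its mean -0.06, and the median turned negative as deposited and after quantile normalization. In it EGR1, a growth-factor induced transcription factor, fell from 357 ± 9.19 (SD, n = 3) to 186 ± 2.82 (SD, n = 3) (log2 fold change -0.94, SE 0.05, adjusted p = 2.20e-05). The nuclear long noncoding RNA NEAT1 rose (log2 fold change 1.03, SE 0.06, adjusted p = 9.10e-05).

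**Figure D2:**
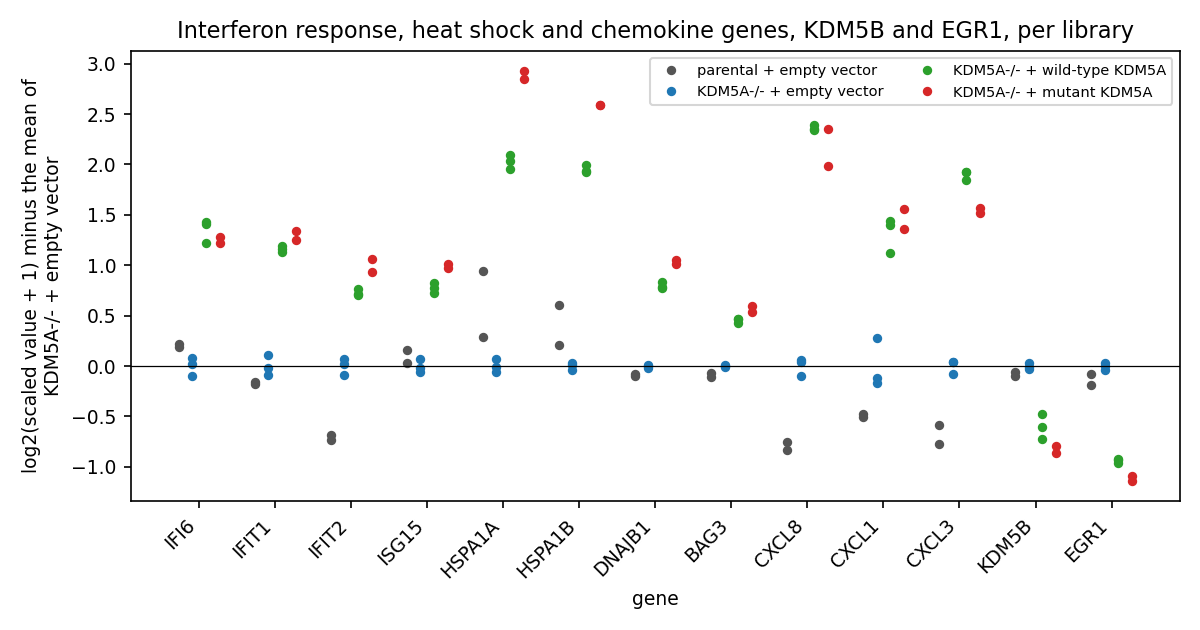
Values of 13 genes in the 10 libraries, as log2(scaled value + 1) minus the mean of the 3 empty-vector knockout libraries, with a point per library coloured by group. CXCL8 rose by 2.36 with wild-type and 2.17 with mutant KDM5A, and KDM5B changed by -0.60 and -0.83.

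The total of 807 genes was 319, 227 and 197 without empty-vector library 1, 2 or 3 and 208, 180 and 204 without wild-type library 1, 2 or 3. It was 2101 with array weights, 1689 with only the 6 libraries of both groups in the fit and 1766 without the mutant libraries and parental library 2, an alternative chosen after seeing the data. The split of 448 higher and 359 lower became 123 higher and 613 lower on the values as deposited. Their median log2 fold change over all genes was -0.10 here, -0.30 for mutant KDM5A against empty vector, -0.19 for mutant against wild-type and -0.07 for parental cells. Of the 33 genes named for this comparison besides KDM5A, 25 passed whichever library was left out. IFI27, PMEPA1, HLA-F, HLA-C, HOXB6, HOXB9, HOXA7 and CDK1 each lost the call without at least 2 of the 6 libraries of these groups and kept their direction, with a highest adjusted p between 0.0586 (CDK1) and 0.148 (HOXA7).

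The comparison of mutant KDM5A with empty vector asks the same of the mutant protein. Heat shock and interferon genes, CXCL8 and CXCL1 rose here too. Most ribosomal protein genes and many genes of oxidative phosphorylation were also higher, in libraries whose make-up stood apart. Those lists did not pass with an estimated correlation. Of the genes tested, 1685 were higher and 1254 lower, together 16.5%. The list counts below are to be read beside that share, and several are not far from it. HSPA1A reached 902 ± 32.3 (SD, n = 2) (log2 fold change 2.89, SE 0.15, adjusted p = 4.04e-05), CXCL8 reached 133 ± 24.0 (SD, n = 2) (log2 fold change 2.17, SE 0.10, adjusted p = 1.40e-05), and KDM5B fell to 14.4 ± 0.559 (SD, n = 2) (log2 fold change -0.83, SE 0.08, adjusted p = 0.00116). The 10 largest rises held KDM5A, HSPA1A and 8 loci that are not protein-coding, and 9 of the 10 largest falls were not protein-coding either.

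Of the 20 heat shock genes, 17 were higher and 0 lower (17 adjusted over the list alone), including HSPA1B (2.59), DNAJB1 (1.04) and BAG3 (0.57). The heat shock list had adjusted p = 0.0414 with an estimated correlation, and its median minus all genes shrank from 0.53 to 0.15 after quantile normalization. Of the 41 interferon response genes, 19 were higher and 1 lower (23 and 1 adjusted over the list alone), including IFIT1 (1.30), IFI6 (1.25), IFIT2 (1.0) and ISG15 (0.99). The interferon list had adjusted p = 0.0121 with an estimated correlation. These were the 2 lists that passed with both correlations. Of the 69 cytosolic ribosomal proteins, 61 were higher and 0 lower (65 adjusted over the list alone), including RPL24 (0.77), RPS7 (0.76) and RPL18 (0.55). The ribosomal protein list had adjusted p = 0.237 with an estimated correlation, and its median minus all genes shrank from 0.55 to 0.03 after quantile normalization. Ribosomal protein genes have many processed pseudogenes, so the share of reads given to each is uncertain. Of the 51 nuclear-encoded oxidative phosphorylation genes, 27 were higher and 0 lower (30 adjusted over the list alone), including SDHB (0.77) and NDUFA4 (0.64). The oxidative phosphorylation list had adjusted p = 0.246 with an estimated correlation, and its median minus all genes shrank from 0.32 to 0.07 after quantile normalization. Of the 13 mitochondrially encoded genes, 10 were higher (12 adjusted over the list alone), including MT-ND3 (0.75). The mitochondrial list had adjusted p = 0.323 with an estimated correlation, and the direction of this list and of MT-ND3 turned downward after quantile normalization. The 7SK RNA RN7SK, a regulator of transcription elongation, was 58.4 and 594 in the mutant libraries against a mean of 20.4 with empty vector, and RN7SL3, an RNA of the signal recognition particle, was 121 and 275 against 25.1. In the list of nuclear and small RNAs 5 of 10 were higher (7 adjusted over the list alone). The small RNA list had adjusted p = 0.237 with an estimated correlation.

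Both mutant libraries and parental library 2 stood apart from the other 7 in their shares of protein-coding and ribosomal protein genes, and not in their mitochondrial share. Protein-coding genes made up 89.6% to 90.3% of the total in these 3 libraries and 92.5% to 92.8% in the others. Ribosomal protein genes made up 15.6% to 16.2% against 12.7% to 14.0%. Mitochondrially encoded genes made up 10.3% to 11.8% against 9.34% to 10.7%, ranges that overlap. Over the members of the 3 lists together, parental library 2 lay above parental library 1 by a median of 0.29 (log2), and the mutant libraries lay above empty vector by 0.50.

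**Figure D3:**
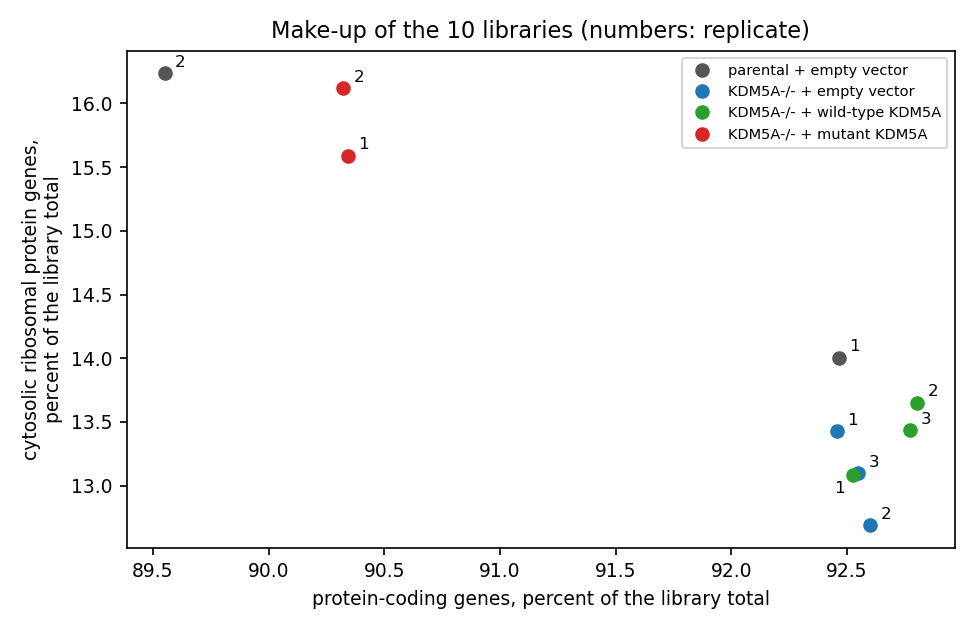
Share of each library's total in cytosolic ribosomal protein genes (vertical axis, percent) against its share in protein-coding genes (horizontal axis, percent), with a numbered point per library. Both mutant KDM5A libraries and parental library 2 lie apart, with protein-coding shares of 90.3% or less against 92.5% or more in the other 7.

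Genes that fell with mutant KDM5A included EGR1 (-1.11), the DNA repair gene BRCA2 (-1.08), the receptor tyrosine kinase AXL (-0.72), the sterol-regulated transcription factor SREBF1 (-0.68), CDC25B (-0.52) and CEBPB (-0.49). In the immediate early list 10 of 35 genes were lower and 3 higher (12 and 3 adjusted over the list alone). The immediate early list had adjusted p = 0.323 with an estimated correlation. HOX genes had 5 of 27 lower and 0 higher (5 adjusted over the list alone), including HOXB6 (-0.57) and HOXA3 (-0.53). The HOX list had adjusted p = 0.0631 with an estimated correlation. G2/M genes had 8 of 40 lower and 4 higher (11 and 4 adjusted over the list alone). The G2/M list had adjusted p = 0.533 with an estimated correlation. The NF-kB list had 8 of 22 higher and 1 lower (8 and 2 adjusted over the list alone), including CXCL1 (1.46). The NF-kB list had adjusted p = 0.233 with an estimated correlation, and its median minus all genes went from 0.12 to 0.00495 without empty-vector library 2. Among 32 p53 targets, 8 were higher and 2 lower (12 and 4 adjusted over the list alone), including GADD45A (0.90). The p53 list had adjusted p = 0.323 with an estimated correlation. The integrated stress list had 12 of 27 higher and 4 lower (12 and 6 adjusted over the list alone), including HSPA5 (0.74), with adjusted p = 0.285 with an estimated correlation and a downward direction after quantile normalization. Antigen presentation genes had 4 of 18 higher (5 adjusted over the list alone). The antigen presentation list had adjusted p = 0.198 with an estimated correlation. MYC targets had 11 of 35 higher and 1 lower (15 and 3 adjusted over the list alone), with adjusted p = 0.115 with an estimated correlation, and turned downward after quantile normalization and, by camera, as deposited. Hypoxia and glycolysis genes had 10 of 31 higher and 1 lower (12 and 1 adjusted over the list alone), with adjusted p = 0.323 with an estimated correlation, and turned downward after quantile normalization. So did housekeeping controls, with 10 of 20 higher (11 higher and 1 lower adjusted over the list alone) and adjusted p = 0.233 with an estimated correlation. With the preset correlation, G2/M genes lost the call without parental library 1 or 2, empty-vector library 1 or mutant library 2 (adjusted p = 0.0642, 0.0699, 0.160 and 0.544), and antigen presentation genes without mutant library 2 (adjusted p = 0.0768). NEAT1 rose (1.11).

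The count of 1685 higher and 1254 lower became 466 higher and 6149 lower on the values as deposited and 887 higher and 1223 lower after quantile normalization. In all, 134 genes passed with the protein-coding share of each library as a covariate, an alternative chosen after seeing the data, and 18 of the 31 genes named here besides KDM5A were among them. Both mutant libraries have the low share and no empty-vector library has it. The covariate therefore also weakens the test, and the fall in number decides nothing. The total of 2939 was 1482 without empty-vector library 2, 1381 without empty-vector library 3, 1207 without mutant library 1 and 1838 with only the libraries of both groups in the fit. Of the 31 genes named besides KDM5A, 25 passed in every fit with a library left out in which they could be tested. The short locus TTC28-AS1_2, listed at 0 outside the mutant libraries, could not be tested without mutant library 1 or 2. MT-ND3, BRCA2 and HOXA3 lost the call without mutant library 1 (adjusted p = 0.0508, 0.0654 and 0.0603) and RN7SL3 without mutant library 2 (adjusted p = 0.0547). HOXB6 lost it without empty-vector library 2 or 3 or mutant library 1 (adjusted p up to 0.101) and RN7SK without empty-vector library 2 or 3 (adjusted p up to 0.0675). The log2 fold change of RN7SK ranged from 1.49 without mutant library 2 to 4.82 without mutant library 1.

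**Figure D4:**
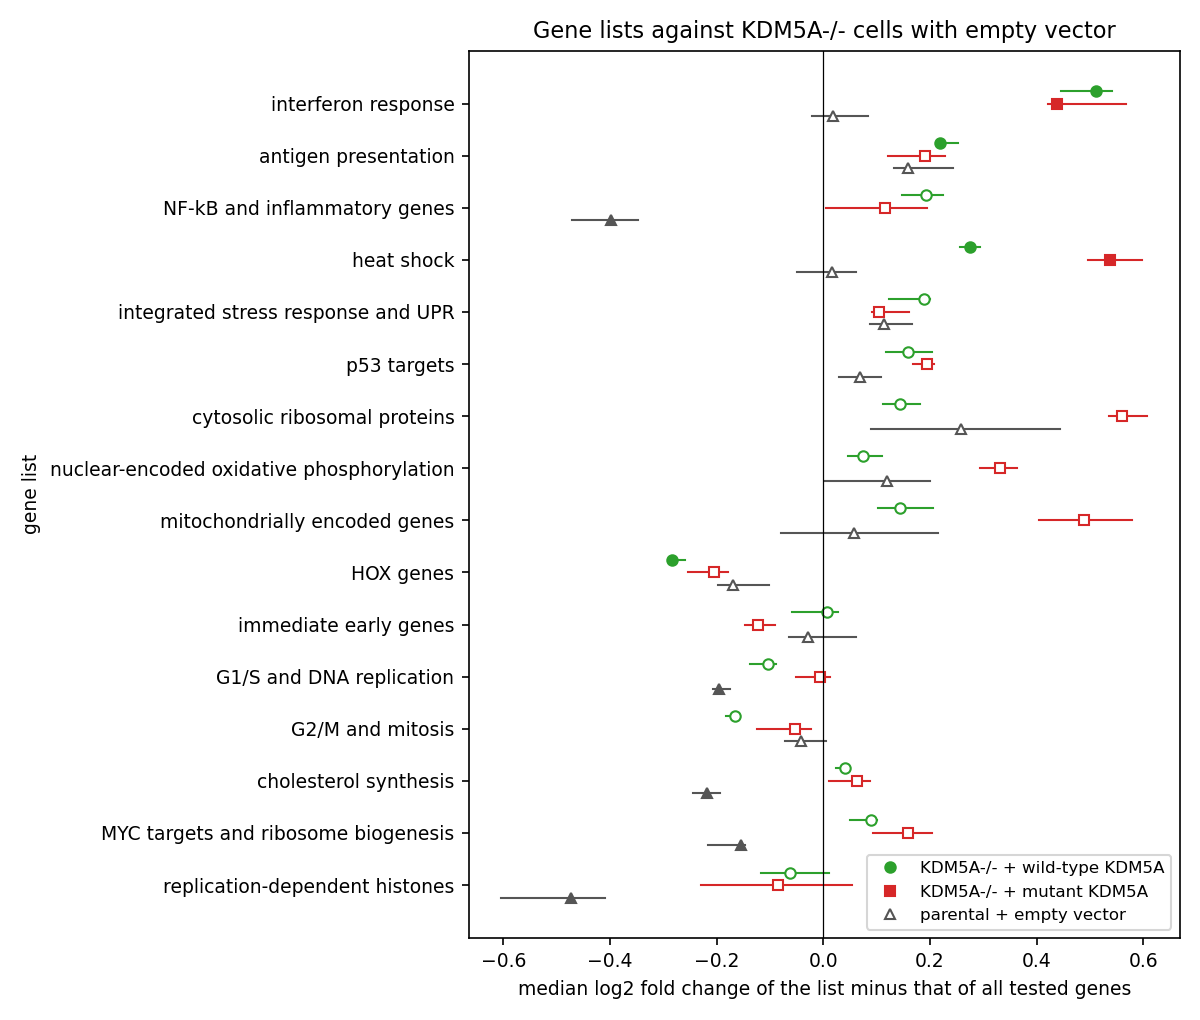
Median log2 fold change of 16 gene lists minus the median of all tested genes (horizontal axis), for wild-type KDM5A, mutant KDM5A and parental cells, each against empty-vector knockout cells. Lines span the values with each library left out in turn, and filled symbols mark lists that passed camera with an estimated correlation, such as the interferon response at 0.51 and 0.44, while the mitochondrial list turned downward in all 3 comparisons after quantile normalization.

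Of the genes that rose with wild-type KDM5A, 346 also rose with mutant KDM5A, where independent lists of the same sizes would share 42.5. Of those that fell, 262 fell with both, against 25.3, and 0 genes were called in opposite directions. Both comparisons use the same 3 empty-vector libraries, which alone bring fold changes together. Across genes, which are not independent replicates, the covariance of the log2 fold changes was 0.0788 (r = 0.532). Unchanged groups simulated with a shared control and a spread pooled over all groups gave 0.0349 (r = 0.448), and the difference was 0.0439. The empty-vector knockout libraries deviated less from their group mean (SD 0.223 to 0.242) than the mutant libraries (0.289). The simulated value is therefore not exact for these controls and may be too high. With 3 control libraries no split leaves at least 2 in each part, so part of the overlap may come from the shared controls.

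The comparison of mutant with wild-type KDM5A sets the 2 plasmids directly against each other. The mutant libraries also differed from the wild-type ones in protein-coding share (90.3% against 92.5% to 92.8%) and in KDM5A level (1.53 times). A difference therefore cannot be assigned to the mutation alone. Few genes passed in this comparison, and none of the genes in the interferon, heat shock, NF-kB, ribosomal protein or HOX lists did. Only 0.056% of all tested genes passed, so the absence of calls in these lists says little about them. The spread was estimated over all 10 libraries. The difference between the 2 parental libraries, outside the comparison, therefore also bore on how many genes passed. Of the 17780 genes tested, 6 were higher and 4 lower with the mutant. Protein-coding genes among them were ANKRD12, an ankyrin repeat protein, which went from 7.05 ± 0.951 (SD, n = 3) to 15.5 ± 2.57 (SD, n = 2) (log2 fold change 1.03, SE 0.13, adjusted p = 0.0497), and VPS13A, a lipid transfer protein, which went from 28.2 ± 2.74 (SD, n = 3) to 14.5 ± 0.588 (SD, n = 2) (log2 fold change -0.90, SE 0.11, adjusted p = 0.0497). HIST2H4B, a histone H4 gene with near-identical copies, went from 8.90 ± 1.21 (SD, n = 3) to 35.0 ± 9.53 (SD, n = 2) (log2 fold change 1.84, SE 0.17, adjusted p = 0.00948). The other 7 were short or noncoding loci. TTC28-AS1_2 (chromosome 22, 27922022 to 27922178), annotated as a miscellaneous RNA, was 519 and 329.9 in the mutant libraries and listed at 0 in the other 8. RN7SL573P was 7.14 and 4.83 and likewise listed at 0 in the other 8. RP11-727F15.13 (4.24 with the mutant, listed at 0 with wild-type, named after its values were seen) and AC005306.3 (0.110 with wild-type and 2.60 with mutant) were higher. EEF1DP2, RP11-114H23.3 and a lincRNA on chromosome 2 (173811076 to 173811392) were lower, with wild-type means of 6.25, 10.3 and 2.88 and mutant values at or near 0.

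Genes below the threshold are given as values. TBL1XR1, a corepressor subunit, had a log2 fold change of -0.50 (adjusted p = 0.0523), HSPA1A 0.86 (0.0806), HSPA1B 0.64 (0.0580), the cystine transporter SLC7A11 -0.45 (0.0580) and RN7SK 2.46 (0.124). ISG15 had 0.22 (0.109), IFIT2 0.27 (0.134), CXCL3 -0.36 (0.119) and KDM5B -0.23 (0.172). RN7SK ranged from 0.80 without mutant library 2 to 4.12 without mutant library 1, where it passed. TBL1XR1, HSPA1A, HSPA1B, SLC7A11, ISG15, RPS18 and RPLP1 passed without parental library 1 or 2, at nearly the same fold changes. With the preset correlation 9 of the 31 lists passed, and 4 of these with the protein-coding share as a covariate. In 0 of the 31 lists did the call hold with an estimated correlation. Ribosomal protein genes made up 15.6% and 16.1% of the mutant libraries and 13.1% to 13.7% of the wild-type ones. Of the 69 ribosomal proteins, 0 passed over all genes and 61 were higher adjusted over the list alone, RPS18 at 0.64 and RPLP1 at 0.63 among those of smallest p. The ribosomal protein list had adjusted p = 2.32e-31 with the preset correlation and adjusted p = 0.417 with an estimated correlation. After quantile normalization its median minus all genes shrank from 0.42 to 0.03, that of heat shock from 0.24 to 0.04 and that of oxidative phosphorylation from 0.22 to 0.12. Counts adjusted over the list alone were 24 of 51 higher for oxidative phosphorylation (adjusted p = 0.417 with an estimated correlation) and 8 of 13 for mitochondrially encoded genes (adjusted p = 0.517 with an estimated correlation, turned downward after quantile normalization). They were 10 of 20 for heat shock (adjusted p = 0.360 with an estimated correlation), and 6 of 35 immediate early genes were lower (adjusted p = 0.417 with an estimated correlation). The interferon list had 0 higher and 2 lower of 41 adjusted over the list alone (adjusted p = 0.995 with an estimated correlation). MYC targets (7 of 35 higher adjusted over the list alone) had adjusted p = 0.417 with an estimated correlation, and hypoxia and glycolysis genes (5 of 31) had adjusted p = 0.517 with an estimated correlation. Both turned from upward to downward after quantile normalization and, by camera, as deposited. Housekeeping controls (8 of 20 higher adjusted over the list alone) had adjusted p = 0.417 with an estimated correlation and turned downward after quantile normalization. With the preset correlation, MYC targets and housekeeping controls lost the call without mutant library 1 (adjusted p = 0.141 and 0.0672). Hypoxia genes lost it without any library but mutant library 2 (adjusted p = up to 0.657, without mutant library 1). The list of nuclear and small RNAs (3 of 10 higher adjusted over the list alone) had adjusted p = 0.417 with an estimated correlation.

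The count of 10 was 974 (692 higher) without parental library 1 and 981 (712 higher) without parental library 2, neither of which is in the comparison. It was 34 without mutant library 2 and 5, 6, 5 and 4 without empty-vector library 1, empty-vector library 2, wild-type library 2 and mutant library 1. It was 214 with only the libraries of both groups, 93 with no filter on low values, 1496 (110 higher) as deposited and 6 (5 higher) after quantile normalization. It was 3 with array weights, 3 with the stricter filter and 1 with the protein-coding share as a covariate. In the main fit 3583 genes had an unadjusted p under 0.05, where independent unchanged genes would give 889. With the share as a covariate 1168 genes had. Both mutant libraries have the low share and no wild-type library has it, so the covariate also weakens the test. The fall in number therefore decides nothing. The excess over 889 cannot be told apart from library make-up, since make-up and plasmid differ between the same libraries. TTC28-AS1_2, RN7SL573P and HIST2H4B passed in every fit with a library left out in which they could be tested, and RP11-727F15.13 lost the call without each wild-type library. AC005306.3, VPS13A and the lincRNA lost the call whichever of the 8 knockout libraries was left out, ANKRD12 and RP11-114H23.3 without 7 of them and EEF1DP2 without 4, at adjusted p up to 0.137, and all kept their direction.

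The comparison of parental cells with knockout cells, both with empty vector, covers the knockout label, the clone and the G418 in the knockout culture together. Genes for cholesterol synthesis, DNA replication, NF-kB signalling, ribosome biogenesis and histones were lower in parental cells, and a group of neighbouring genes on chromosome X was near 0 in every library labelled KDM5A-/-. Of the genes tested, 728 were higher and 861 lower in parental cells, together 8.94%. LIPG, an endothelial lipase, was 17.4 ± 1.80 (SD, n = 2) in parental cells and 0.195 ± 0.0483 (SD, n = 3) in knockout cells (log2 fold change 3.94, SE 0.18, adjusted p = 2.41e-05), and SPARC, a matrix glycoprotein, was 0.463 ± 0.0598 (SD, n = 2) against 7.48 ± 1.0 (SD, n = 3) (log2 fold change -2.53, SE 0.15, adjusted p = 9.29e-05). The pseudogene GNG5P2 was 22.8 and 70.9 in the parental libraries and listed at 0 in the other 8. The matrix metalloproteinase MMP14 (2.82) and FAM221A (2.62) were among the 10 largest rises and the protease TMPRSS13 (-1.96) among the 10 largest falls.

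On chromosome X (GRCh38), CA5BP1 (15674932 to 15703724), CA5B (15688830 to 15787624), AC112497.1 (15702602 to 15703243) and the splicing factor gene ZRSR2 (15790472 to 15823260) were near 0 in the knockout libraries. Their parental means were 17.4, 2.90, 5.24 and 9.11, and the highest values in any of the 8 knockout libraries were 0.197, 0.0442, 0.313 and 0.630. The largest adjusted p of the 4 was 0.00110, and ZRSR2 had a log2 fold change of 2.79 (SE 0.19). The first 3 overlap and can share reads, so they are uncertain as separate genes. The flanking genes PIR and AP1S2, chosen with CA5B after the values were seen, were 40.6 and 22.0 in parental cells and 31.2 and 19.3 with empty vector in knockout cells, and neither passed (adjusted p = 0.0589 and 0.491). PIR, at 0.37, was 0.50 without parental library 1, where it passed, and 0.23 without parental library 2. It also passed without either mutant library.

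**Figure D5:**
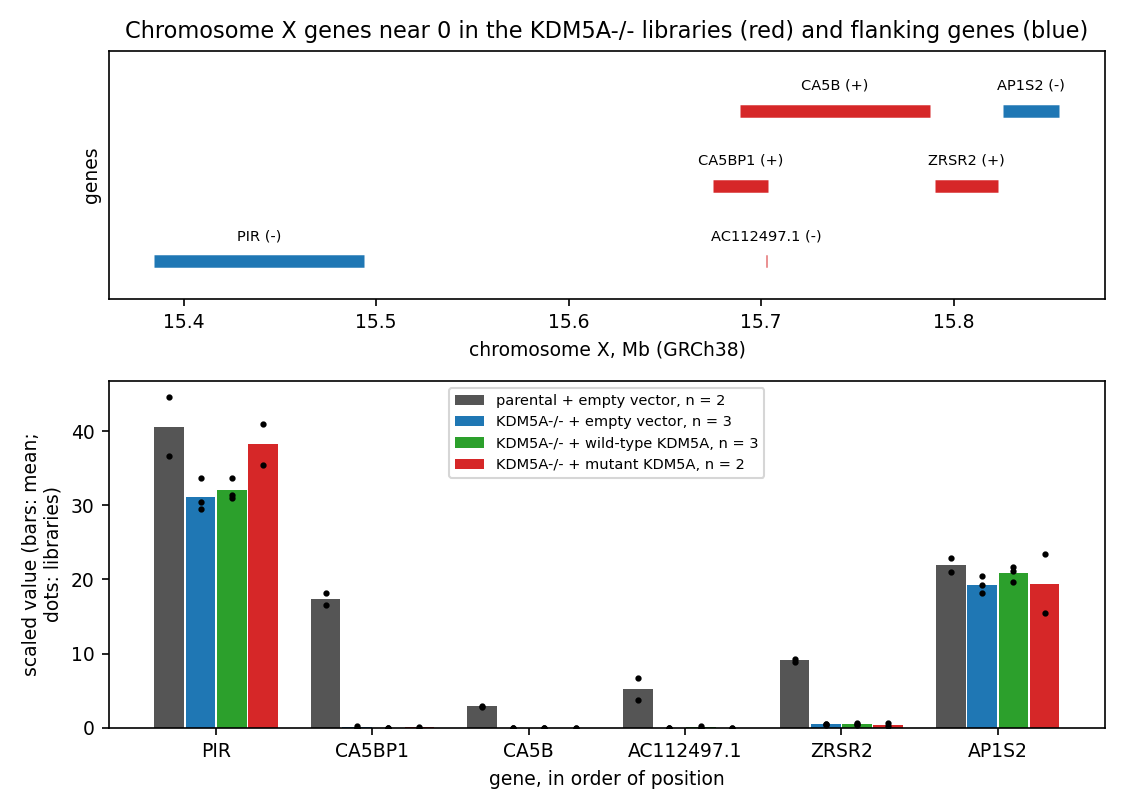
Position of 6 genes on chromosome X in GRCh38 (upper panel, Mb) and their scaled values (lower panel), with bars for group means and dots for libraries. CA5BP1, CA5B, AC112497.1 and ZRSR2 stay at or below 0.630 in the 8 knockout libraries, and the flanking PIR and AP1S2 stay at or above 15.5.

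Of the 29 cholesterol synthesis genes, 11 were lower and 1 higher in parental cells (17 and 1 adjusted over the list alone), including ACAT2 (-0.64) and FDPS (-0.40). The cholesterol list had adjusted p = 0.0378 with an estimated correlation, and the exception was SQLE, squalene epoxidase (0.82). Of 46 G1/S and DNA replication genes, 10 were lower and 0 higher (19 and 1 adjusted over the list alone), including the helicase subunits MCM5 (-0.60) and MCM2 (-0.46) and the licensing factor CDT1 (-0.43). The G1/S list had adjusted p = 0.0378 with an estimated correlation. Of 22 NF-kB and inflammatory genes, 10 were lower and 2 higher (12 and 2 adjusted over the list alone), including BIRC3 (-1.02), CXCL8 (-0.79), the inhibitor NFKBIA (-0.78) and RELB (-0.62). The NF-kB list had adjusted p = 0.0378 with an estimated correlation. MYC targets and ribosome biogenesis genes had 12 of 35 lower and 0 higher (12 adjusted over the list alone), including RRP12 (-0.41) and NOLC1 (-0.36). The MYC list had adjusted p = 0.0417 with an estimated correlation. Replication-dependent histones had 5 of 36 lower (6 adjusted over the list alone), including HIST1H1C (-0.94) and HIST1H2BK (-0.86). The histone list had adjusted p = 0.0417 with an estimated correlation, and these copies share sequence. These 5 lists passed with both correlations. With the length correction, chosen after seeing the data, and an estimated correlation, 3 lists passed in this comparison. Homologous recombination genes had 3 of 33 lower and 1 higher (the same counts adjusted over the list alone). The recombination list had adjusted p = 0.0881 with an estimated correlation. Antigen presentation genes had 6 of 18 higher (7 higher and 1 lower adjusted over the list alone), HLA-F at 0.88 among them. The antigen presentation list had adjusted p = 0.251 with an estimated correlation. Oxidative phosphorylation (4 of 51 higher, 4 adjusted over the list alone, adjusted p = 0.773 with an estimated correlation) and ribosomal proteins (0 of 69, 0 adjusted over the list alone, adjusted p = 0.636 with an estimated correlation) also passed upward with the preset correlation. Their medians minus all genes shrank from 0.12 to 0.05 and from 0.26 to 0.04 after quantile normalization. Without parental library 2 they were 0.00391 and 0.09, and without parental library 1 0.20 and 0.44. With the preset correlation, oxidative phosphorylation lost the call without parental library 2, empty-vector library 2 or empty-vector library 3 (adjusted p = 0.758, 0.102 and 0.0544). Antigen presentation lost it without parental library 1 or any empty-vector library (adjusted p = up to 0.223, without parental library 1), and homologous recombination without parental library 1 (adjusted p = 0.101).

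Other named genes that differed were the epithelial transcription factors EHF (1.69) and ELF3 (-0.83), the interferon-induced SAMD9 (-1.53), HOXA3 (-1.45), GDF15 (0.91), the kinase PLK2 (-1.21), the phosphatase DUSP6 (0.99) and FOSB (-1.17). KDM5B did not pass (-0.08, adjusted p = 0.597). The interferon list (3 higher and 5 lower of 41, 5 and 6 adjusted over the list alone, adjusted p = 0.991 with an estimated correlation) and the heat shock list (2 higher and 1 lower of 20, the same adjusted over the list alone, adjusted p = 0.991 with an estimated correlation, with a median below 0 after quantile normalization) did not pass. The total of 1589 was 636 without parental library 2, and 949, 831 and 712 without empty-vector library 1, 2 or 3. It was 464 with only the libraries of both groups, 1042 with array weights and 620 with the protein-coding share as a covariate, which kept 30 of the 33 named genes. The split of 728 higher and 861 lower became 374 and 972 on the values as deposited. Of the 33 named genes that passed, 31 passed in every fit with a library left out in which they could be tested. CA5BP1, CA5B, AC112497.1, ZRSR2, GNG5P2, LIPG and FAM221A fell under the filter without parental library 1 or 2. For these genes the calls were not checked against the loss of a parental library. CDT1 lost the call without parental library 2 (adjusted p = 0.0561) and HLA-F without parental library 2 or empty-vector library 3 (adjusted p up to 0.0808).

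Fold changes were also compared between the KDM5A plasmids and the parental state, since both are set against the same empty-vector libraries. For wild-type KDM5A the covariance with the parental fold changes was 0.0339 (r = 0.263). Unchanged groups simulated with the pooled spread gave 0.0346 (r = 0.444), a difference of -0.000658. The parental and mutant libraries deviated more from their group means (SD 0.256 and 0.289) than the empty-vector knockout libraries (0.223 to 0.242). The simulated values may thus be too high, and the sign of so small a difference decides nothing. For mutant KDM5A the covariance was 0.0530 against 0.0351, a difference of 0.0179. It was 0.0259 without parental library 2, below the simulated value, and 0.0806 without parental library 1. Of the genes higher with wild-type KDM5A, 57 were higher and 57 lower in parental cells, and of the genes lower with it, 96 were lower and 18 higher. Independent lists would share 18.3, 21.7, 17.4 and 14.7. The fold changes of mutant against wild-type KDM5A, which share no library with the parental comparison, had a covariance with it of 0.0191 (r = 0.119). It turned to -0.00523 without parental library 2 and was 0.0444 without parental library 1.

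The remaining lists did not pass camera in any of the 4 comparisons with either correlation. None of their members passed between mutant and wild-type KDM5A, where only 10 of the 17780 genes tested did. Some passed with fry. Among them with wild-type KDM5A were H3K4 methylation (adjusted p = 0.0476, upward), apoptosis (0.0478, upward) and metallothioneins (0.00548, downward). With mutant KDM5A the genes described for KDM5A passed with fry (0.0153, upward). The H3K4 methylation machinery had 1 of 29 genes higher with wild-type KDM5A, 5 higher and 1 lower with mutant KDM5A and 2 higher and 1 lower in parental cells (smallest adjusted p = 0.0590 by camera). This list holds methyltransferase genes and also the demethylases KDM1A and KDM1B and the corepressor genes SIN3A, SIN3B, HDAC1 and HDAC2. With wild-type KDM5A the H3K4 list passed without empty-vector library 2, wild-type library 2 or either mutant library (smallest adjusted p = 0.0302, without empty-vector library 2). Genes described as bound or regulated by KDM5A had 1 higher and 1 lower of 23, 4 higher and 1 lower, and 2 lower in the same order (smallest adjusted p = 0.338 by camera). CDK inhibitors and the RB family (18 genes) had 1 higher, none, and 2 higher and 3 lower. Wnt targets (17) had 1 lower, 1 higher and 3 lower, and 4 higher and 1 lower, and the Notch pathway (15) had none, 2 lower and 2 higher. Without parental library 2, Wnt targets and the Notch pathway passed in parental cells, with medians of 0.20 and 0.19 (adjusted p = 0.0252 and 0.0160), while without parental library 1 the medians were 0.05 and -0.08 and neither passed. Intestinal differentiation genes (6) had none, 1 higher and 1 lower, and metallothioneins (8) had 1 higher and 2 lower, 1 lower and none. Apoptosis regulators (29) had 4 higher and 1 lower, 3 higher and 1 lower, and 2 higher and 4 lower. They passed with wild-type KDM5A without wild-type library 2 or either mutant library (smallest adjusted p = 0.0358, without wild-type library 2), and their median of 0.06 shrank to 0.00591 without empty-vector library 2. Markers of other cultured lines (7 tested) had none, 1 higher and 1 higher. The KDM5 paralogs, germline genes, blood markers and fibroblast and endothelial markers had 3, 4, 3 and 1 genes above the filter, too few for camera. Besides KDM5A and KDM5B, those passing were 1 blood marker higher with wild-type and with mutant KDM5A, 1 fibroblast or endothelial marker lower with mutant KDM5A, and 1 germline gene higher and 1 lower in parental cells.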

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

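Of the tests in this part, the comparison of the parental libraries with each other and the covariate were chosen after the results were seen, and the length test was set before its result was seen. The 10 genes that differed between mutant and wild-type KDM5A by a direct limma test of the difference had the values that follow, as fitted differences of log2(value + 1), which are not folds where a group is listed at 0. TTC28-AS1_2 had 8.70 with the mutant (higher in 2 of 2 mutant libraries, listed at 0 in all 3 wild-type libraries). RN7SL573P had 2.78, with 0 listed in the wild-type libraries as well. RP11-727F15.13 had 2.39, also against 0. HIST2H4B had 1.84, AC005306.3 1.70 and ANKRD12 1.03. VPS13A had -0.90, the lincRNA on chromosome 2 (173811076 to 173811392) -1.92, EEF1DP2 -2.82 and RP11-114H23.3 -3.45, and the lincRNA and RP11-114H23.3 were listed at 0 in both mutant libraries. AC005306.3 was also above 0 in the parental libraries, at 3.89 and 3.11. Mutant and wild-type libraries also differed in make-up and KDM5A level, so these differences cannot be assigned to the mutation alone.

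Ribosomal protein, oxidative phosphorylation and mitochondrially encoded genes were higher with mutant KDM5A than with empty vector, in libraries whose make-up also stood apart, and the lists had adjusted p = 0.237, adjusted p = 0.246 and adjusted p = 0.323 with an estimated correlation. The length correction argues against a trend with gene length as the whole cause, since after it the median of the ribosomal list was 0.563 (jackknife SE 0.0594) against 0.559 without it. The make-up of the libraries is a candidate explanation. Parental library 2, which holds no KDM5A plasmid, lay above parental library 1 by a median of 0.289 (log2) over the members of the 3 lists, against 0.501 for mutant KDM5A. Its ribosomal protein share was already known to be higher than that of parental library 1 (16.2% against 14.0%). For the ribosomal genes this median therefore restates the make-up and is no separate support. With the protein-coding share of each library as a covariate, the ribosomal median was 0.323, and after quantile normalization it was 0.03 while the mitochondrial median turned to -0.268. An effect of mutant KDM5A on these genes stays open and untested, since both mutant libraries share the make-up.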

How the results depend on the processing

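The corrections for gene length and library make-up, the fit without the 3 libraries of lower protein-coding share and quantile normalization of the lists were chosen after seeing the data. DESeq2 was not run, since the values are normalized. The cause was not tested for any change below unless the setting itself sets the number of genes, lists or libraries. Of the 107 calls of named genes besides KDM5A (a gene counts once in each comparison), 105 passed as deposited, 98 after quantile normalization, 104 and 106 with pseudocounts of 0.1 and 0.5, 97 without a filter, 90 of 93 with the stricter filter, 100 with array weights, 99 with only the libraries compared, 89 with a replicate block (26 of 33, 30 of 31, 1 of 10 and 32 of 33 in the order of comparisons below), 53 at a log2 fold change of at least 1, 107 at an adjusted p under 0.1, 103 with the length correction and 82 with the make-up covariate (33 of 33, 18 of 31, 1 of 10 and 30 of 33 in that order). MT-ND3 (mutant against empty vector) turned to -0.0386 after quantile normalization, and no other named gene turned. Leaving out each library gave 951 of 1048 calls. A group left with 1 library is assumed to vary like the others. The unknown depth limits what the low values can show.

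Genes that passed, in the order wild-type against empty vector, mutant against empty vector, mutant against wild-type and parental against knockout, were 1570, 4484, 643 and 2727 at an adjusted p under 0.1. Those with a log2 fold change of at least 1 were 48, 273 and 145 (first, second and last comparison). With only the libraries compared they were 1689, 1838, 214 and 464. Array weights gave 2101, 3 and 1042 (all but mutant against empty vector). Values as deposited gave 6615 and 1496 for the comparisons with mutant KDM5A. For mutant against wild-type, quantile normalization gave 6, no filter 93, the stricter filter 3 and the length correction 6. The make-up covariate gave 134, 1 and 620 (second to last). The fit without 3 libraries gave 1766 in the first comparison, 806 of them among its 807. With a replicate block the counts were 214, 1109, 1 and 556. The pairing by replicate number has no basis in the values: over 13 pairs of libraries with the same number the correlations of their residuals ran from -0.0892 to 0.0509. Leaving out 1 library gave 180 (without wild-type library 2) to 1069 (without parental library 1), 1207 (without mutant library 1) to 3495, 4 (without mutant library 1) to 981 (without parental library 2), and 636 (without parental library 2) to 1925.

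KDM5A kept its calls except between mutant and wild-type, with ranges over left-out libraries of 9.99 to 10.15, 10.61 to 10.76, 0.53 to 0.67 and 0.01 to 0.39 (log2). The difference of 0.62 between mutant and wild-type did not pass in the main fit. It passed at an adjusted p under 0.1 and, as given above, without parental library 1 or 2. Lists that passed numbered 17, 16, 9 and 9, 4, 2, 0 and 5 with an estimated correlation, and 19, 18, 7 and 9 with fry. With the length correction and an estimated correlation they were 3, 3, 0 and 3. Wild-type KDM5A had 10 after quantile normalization and 4 without the 3 libraries and with an estimated correlation, and mutant against wild-type had 4 with the covariate. Leaving out 1 library gave 14 to 21, 14 to 16, 7 to 11 and 7 to 15 (without parental library 2). The covariance of fold changes with a pseudocount of 0.1 was 0.113 (wild-type with parental), 0.155 (mutant with parental) and 0.199 (wild-type with mutant). Leaving out 1 library gave 0.0311 to 0.0487, 0.0259 (without parental library 2) to 0.0806 (without parental library 1), 0.0757 to 0.0945, and for mutant against wild-type with parental -0.00523 (without parental library 2) to 0.0444.

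Lists that passed with or without quantile normalization and whose camera direction turned with it had these medians after it. With wild-type KDM5A oxidative phosphorylation was -0.0326, mitochondrial genes -0.134, ribosomal proteins -0.0277, MYC targets -0.0111 and housekeeping -0.00528. With mutant KDM5A the stress response was -0.0768, hypoxia -0.0221, mitochondrial genes -0.268, MYC targets -0.0454, epithelial genes -0.0788, cholesterol synthesis -0.142 and housekeeping -0.107. Between mutant and wild-type hypoxia was -0.0165, mitochondrial genes -0.0254, MYC targets -0.00989 and housekeeping -0.0821. In parental cells mitochondrial genes were -0.118, and -0.0798 to 0.215 over left-out libraries, the lowest without parental library 2. Other medians changed sign after it, among them epithelial genes -0.0171, hypoxia -0.0142 and immediate early genes -0.0297 with wild-type KDM5A and housekeeping -0.114 and heat shock -0.0597 in parental cells. As deposited, camera turned MYC targets and cholesterol synthesis with mutant KDM5A (medians minus all genes 0.113 and 0.0136) and hypoxia and MYC targets between mutant and wild-type (0.0415 and 0.0470).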

Other observations

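The symbol families, the tests of plasmid load and protein-coding share and those of the chromosome X genes were chosen after the results were seen, and the length and split tests were set before their results were seen. Families of genes with a shared symbol stem and at least 15 tested members hold groups not covered by the fixed lists. Of 332 tests of 83 families over the 4 comparisons, 42 passed camera with the preset correlation and 0 with an estimated correlation. Of 369 zinc finger genes of the ZNF family, 24 were lower and 3 higher with wild-type KDM5A against empty vector (median -0.13, adjusted p = 4.28e-05 with the preset correlation and adjusted p = 0.369 with an estimated correlation). Of 54 translation initiation factor genes (EIF), 18 were higher and 2 lower with mutant KDM5A (median 0.20, adjusted p = 0.482 with an estimated correlation), a median that shrank to 0.01 after quantile normalization. Of 35 DEAD-box helicase genes (DDX), 11 were lower and 1 higher in parental cells than in knockout cells, and of 34 RNA-binding motif genes (RBM), 7 were lower and 1 higher (medians -0.16 and -0.18, adjusted p = 0.419 for both with an estimated correlation).

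Interferon response and heat shock genes were higher with both KDM5A plasmids than with empty vector. The length correction argues against a trend with gene length as the whole cause, as the smallest of the 4 medians was 0.284 after the correction and 0.276 before it (jackknife SE 0.0277). A lower share of protein-coding genes does not account for the rise with wild-type KDM5A, as the share was 0.166 percentage points higher with it than with empty vector (SE 0.0967), against a difference of -2.20 for mutant KDM5A, where this stays open (heat shock median 0.440 with the share as a covariate) since both mutant libraries have the low share. Plasmid or protein load without regard to what KDM5A does stays open. Besides the GFP used for sorting, no library is labelled as carrying an unrelated protein in place of KDM5A. The labels also do not say whether the mutant is inactive. Between mutant and wild-type KDM5A the heat shock median was 0.244 (jackknife SE 0.124, 0.144 without mutant library 1 and 0.0413 after quantile normalization) and the interferon median -0.02. A response to KDM5A itself may also account for the rise and was not tested apart from load.

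Over the 10 splits of the 6 wild-type and empty-vector libraries into 3 and 3, the real split called 807 genes and the highest other split 1, the number of splits with as many genes was 1, and 10 splits are too few for a share under 0.05.

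CA5BP1, CA5B, AC112497.1 and ZRSR2 lie within 148 kb of chromosome X and were near 0 in every library labelled KDM5A-/-. In 10000 random placements of the 8 loci near 0 in all knockout libraries among 12804 loci, 0.46% gave a pair of neighbours, which argues against chance neighbours. Wild-type KDM5A did not bring the genes back within 24 hours, as the mean of the 4 genes with it was 1.71% of the parental mean. Loss of the DNA segment in the knockout clone is a candidate explanation. No knockout library had a gene of the segment above 6.92% of its parental mean, while PIR and AP1S2 beside it stayed at 15.5 or more in every knockout library. ZRSR2 was above 0 in each of the 8 knockout libraries, at 0.225 to 0.630, and the source of these low values was not tested. Stable silencing would look the same in RNA as loss of the segment, so these cannot be told apart.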
